A study of Homo sapiens with 30 samples.

How the data were processed

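RNA of the human osteosarcoma cell line U2OS was measured on 30 single-colour Illumina bead arrays, on which each gene is read by probes attached to beads. Per the labels' protocols, cells were infected with retroviruses that express short hairpin RNAs (shRNAs), and 2 days later were exposed to 5 Gy from a caesium source or to a mock treatment. Total RNA was taken 4 h after that, amplified and labelled with biotin. The first experiment holds 24 arrays in 8 groups of 3: a control shRNA, an NFBD1 shRNA (hairpin b), a p53 shRNA, and the NFBD1 and p53 shRNAs together, each at 0 and at 5 Gy. The second experiment holds 6 unirradiated arrays in 2 groups of 3, another NFBD1 hairpin (called the second hairpin here) and its own control. Groups and replicate numbers were taken from the sample titles, and chips from the array labels.

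The authors deposited a table of probe intensity, the mean signal over a probe's beads, which per the file headers and its values was neither background-subtracted nor normalized between arrays. The same deposited table gives a detection p-value for each probe and array, which per the file headers compares the probe with negative controls. Its 60 further columns, of 2 kinds (the standard error over beads and the number of beads), were not used. The authors also deposited a matrix of processed values on a log2-like scale, with no word on how it was made. Its values ranked the probes of each array exactly as the signal did (Spearman 1), had a common distribution on all arrays (sorted columns differed by at most 0.00106) and a median of 6.951 on every array. They were not centred on 0, differences between arrays ran the same way as in the signal, and the transformation applied to low signals stays unknown. That matrix served as an alternative. The scanner software and its settings are not given in the sources used here.

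Of 48802 probes, 27577 had 1 gene symbol in the platform annotation, 13 had several and 21212 had none; only the first kind was named. The gene identifiers of 27540 probes matched the RefSeq gene table (assembly GRCh38.p14), which was used only for current symbols. MDC1, the gene of NFBD1, had 1 named probe. The p53 transcript itself was not analysed here. No genome build is named for this series, so no positions are given.

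Intensities were background-corrected against the negative controls as inferred from the detection p-values, quantile-normalized and put on the log2 scale with limma's neqc (limma 3.58.1 in R 4.3.3, offset 16), within each experiment. Probes with a detection p-value under 0.01 on at least 3 arrays were kept (21568 in the first experiment, 17975 in the second), and each gene was read from its kept probe with the highest mean, which left 12419 and 11040 genes, 10910 of them in both. Group means were fitted with limma's lmFit and eBayes over all groups of an experiment (16 and 4 residual degrees of freedom). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. There were 15 comparisons, 4 of them interactions, that is, differences between 2 such changes. A probe below background on every array of a group has only a bound there: the brighter group's mean was set against the mean of, per array, the higher of the lowest signal among detected probes and the probe's own signal, and the result is given as "at least N-fold". Where other detected probes of a named gene moved the opposite way, this is said.

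The genes named follow a fixed rule: MDC1; the 8 largest rises and 8 largest falls among called genes whose arrays did not overlap between groups, leaving out provisional symbols; up to 4 called members of each gene list, or 2 members as values where none was called; and the 3 genes with the smallest p where a comparison called none. Genes outside the rule are said to be chosen after their values were seen. The 16 gene lists were p53 targets, G2/M and mitosis, DNA replication and G1/S, DNA damage signalling and repair, replication-dependent histones, interferon response, NF-kB and inflammatory genes, immediate early genes, apoptosis regulators, endoplasmic reticulum (ER) stress and amino acid response, cholesterol synthesis, extracellular matrix and TGF-beta, epithelial markers, blood cell markers, neural and HEK293-type markers, and housekeeping genes. Of 73 listed p53 targets, 70 had a named probe, as had 65 of 65 G2/M genes. CCN2, CLSPN, DDIT4 and SESN2 stood on 2 lists each. Lists were tested with limma's camera, which asks whether a list moved against the other genes, with an inter-gene correlation of 0.01, adjusted over all 240 list tests. Called members are counted over all genes and adjusted over the list alone. With the correlation estimated from the data, 17 of the 37 list calls held: p53 targets and G2/M in the 4 irradiation comparisons, p53 targets in both comparisons of the p53 shRNA and in the irradiation by p53 interaction, ER stress with hairpin b at 5 Gy, with hairpin b in p53-depleted cells at both doses and with the p53 shRNA at 5 Gy, histones after irradiation with the p53 shRNA, and G2/M with the second hairpin.

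Each array had 16622 to 19662 detected probes, 34.1% to 40.3% of all, and a median signal of 36.7 to 63.7 intensity units. Arrays lay on 5 chips of 6. Chips 1 and 2 had median signals of 56.9 to 63.7, chip 3 of 46.5 to 50.2, chip 4 of 49.4 to 53.5 and chip 5, which held the whole second experiment, of 36.7 to 43.5. In the first experiment the chip accounted for 95% of the first principal component (24% of the variance) and the group for 87.9% of the second (11.9%). The 0 and 5 Gy arrays of a replicate shared a chip, and each of chips 1 to 4 held 3 of the 4 shRNA treatments, so the chip was fitted as a block and differences were also taken within chips. No 2 arrays held identical signals. The number of arrays limits the precision: the median standard deviation within groups was 0.205 log2 units in the first experiment and 0.095 in the second. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

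The fit and its calls were tested on simulated data, in 5 runs of 200 genes seeded with known changes. Independent noise was added to normalized gene means, without chip effects or correlation between genes. Background correction, normalization, the detection filter and the interactions were therefore not tested, and the rates may be better than in the real data. For irradiation with the control shRNA (12419 genes), 26.8%, 88% and 99.4% of log2 changes of 0.5, 1 and 2 were recovered, with 6.42% false calls. For the second hairpin (11040 genes) these were 72.3%, 96.8% and 100%, with 3.75% false calls. Replicate numbers are shared between groups. Deviations from the group means correlated above 0.1 for every same-numbered pair in 7 of the 10 comparisons of 2 groups in the first experiment (range over all pairs -0.141 to 0.626), where the numbers were taken to pair the samples. The exceptions were irradiation with the control shRNA and both comparisons of the p53 shRNA. Same-numbered arrays of the 2 doses shared a chip, as did some of different shRNAs, so these correlations can come from the chip. They do not show that a number marks 1 culture. The main tests did not use the pairing, and the replicate block is given as an alternative.

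The comparisons, gene lists, naming rule and most alternatives were fixed before the data were examined. Alternatives were no background correction, the authors' values, all 30 arrays normalized together, no or a stricter detection filter, each probe tested on its own, moderation with trend and robust options, only the groups compared, the chip or the replicate number as a block, differences within a chip, and each array left out in turn. Correlations of fold changes are across genes, which are not independent replicates. They were computed for 6 pairs of comparisons, none of which shares an array, and for 4 more pairs added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.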

Results

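Messenger RNA was measured in U2OS cells, a human osteosarcoma line, on 30 bead arrays in 10 groups of 3. Short hairpin RNAs against NFBD1 (gene MDC1, a chromatin-bound mediator of the DNA damage checkpoint) and against p53 were used alone and together, with and without 5 Gy of ionizing radiation, and a second NFBD1 hairpin was run with its own control. Each array detected 34.1% to 40.3% of the 48802 probes. The stated questions were what part NFBD1 plays in gene expression with and without radiation, and which of the changes depend on p53. Fold changes are given with the standard error of the log2 change from limma, and adjusted p-values are Benjamini-Hochberg values.

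The MDC1 transcript was lower with each NFBD1 hairpin. Its log2 intensity was 9.01 ± 0.28 (SD, n = 3) with the control shRNA and 7.59 ± 0.48 with hairpin b in unirradiated cells, and 8.98 ± 0.45 and 7.14 ± 0.08 after 5 Gy. It was 8.67 ± 0.39 with the p53 shRNA and 7.49 ± 0.06 with both shRNAs in unirradiated cells, and 8.70 ± 0.23 and 7.52 ± 0.28 after 5 Gy. In the second experiment it was 8.65 ± 0.12 in the control and 6.24 ± 0.08 with the second hairpin. MDC1 fell 2.67-fold with hairpin b (log2 -1.42 ± 0.24 SE, limma adjusted p = 0.00303), 3.59-fold after 5 Gy (-1.84, adjusted p = 0.000137), 2.26-fold in p53-depleted cells at either dose (-1.17, adjusted p = 0.0185, and -1.18, adjusted p = 0.0153) and 5.31-fold with the second hairpin (-2.41 ± 0.08 SE, adjusted p = 6.43e-07). With the chip as a block the first 4 log2 changes were -1.32, -1.74, -1.27 and -1.27. Within chips they were -1.67 and -1.12, then -1.44 and -1.89, then -1.39 and -0.78, then -1.12 and -1.19. In p53-depleted cells the MDC1 call was lost at 0 Gy without p53 replicate 1 or 2 or any of the 3 double-depleted arrays (adjusted p 0.061 to 0.131), and at 5 Gy without p53 replicate 2 or 3 or double-depleted replicate 1 or 3 (0.065 to 0.105). MDC1 was not called changed by irradiation or by the p53 shRNA: the log2 changes after 5 Gy were -0.03 with the control shRNA and -0.45 with hairpin b (limma adjusted p = 0.486).

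**Figure D1:**
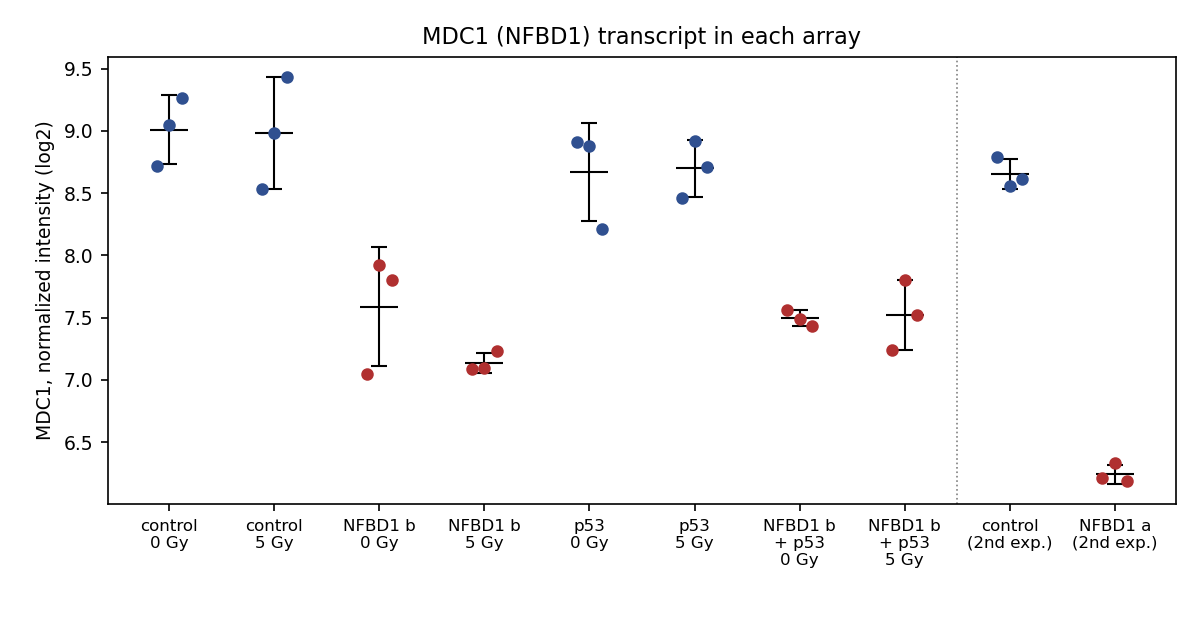
Log2 intensity of MDC1 on each array (points) with the mean and SD of each group of 3 arrays, groups on the horizontal axis; the dotted line separates the second experiment, which was normalized on its own. Group means lay between 7.14 and 7.59 with hairpin b and between 8.67 and 9.01 without it in the first experiment.

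The response to radiation was first taken in cells with the control shRNA, 4 h after 5 Gy (n = 3 against 3). Genes known as p53 targets rose and genes of mitosis fell. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, rose 3.30-fold (log2 1.72 ± 0.18 SE, limma adjusted p = 8.4e-06), from 11.69 ± 0.36 to 13.41 ± 0.11 (SD). MDM2, the ubiquitin ligase that limits p53, rose 2.49-fold (1.32 ± 0.22, adjusted p = 0.00212), GDF15, a secreted stress cytokine, 2.91-fold, SESN1, a sestrin, 2.52-fold, PPM1D, the WIP1 phosphatase, 2.21-fold, and ATF3, a stress-induced transcription factor, 2.54-fold. INKA2 rose 2.73-fold and TP53INP1 2.78-fold. The DNA helicase gene PIF1 fell 3.03-fold (-1.60 ± 0.14, adjusted p = 1.33e-06), from 7.86 ± 0.15 to 6.26 ± 0.38. CENPA, the centromeric histone, fell 2.43-fold, CCNB1, the mitotic cyclin B1, 2.10-fold (-1.07 ± 0.17, adjusted p = 0.00175), the spindle genes FAM83D and PSRC1 2.30-fold and 2.13-fold, BORA, an activator of Aurora A, 2.19-fold, and CDCA8, a subunit of the chromosomal passenger complex, 2.06-fold. TNFAIP8L1 fell 2.08-fold.

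Of the 62 tested p53 targets, 16 rose after irradiation with the control shRNA (33 adjusted over the list alone) and none fell. The median log2 change was 0.46, and 0.42 to 0.62 within chips (camera adjusted p = 4.97e-65, or 2.64e-06 with an estimated correlation). Of 65 G2/M genes, 27 fell (44 adjusted over the list alone). Their list had a median of -0.41, and -0.58 to -0.40 within chips (camera adjusted p = 5.96e-97, or 2.64e-06 with an estimated correlation). The 17 replication-dependent histone genes had a median of -0.18, and -0.30 to -0.02 within chips (camera adjusted p = 0.000163; adjusted p = 0.117 with an estimated correlation), with none of them called. In all, 26 genes rose and 47 fell of 12419, and with the chip as a block 44 rose and 64 fell. All 73 called genes changed the same way within each of the 3 chips, and none had overlapping arrays between doses, where 8.58% of all genes were free of overlap (10% by chance). Where arrays do not overlap, the direction within a chip is fixed, so this agreement is no separate check on the chip. The same applies to the comparisons below, where nearly all called genes had no overlap. The count was 40 without unirradiated replicate 2 and 46 without unirradiated replicate 3, and the TP53INP1 call was lost without either of these or irradiated replicate 3 (adjusted p 0.0622 to 0.0672). Here and below, fitting only the 6 arrays compared leaves 4 residual degrees of freedom in place of 16; it called 28 genes, without MDM2 and TNFAIP8L1.

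With hairpin b, irradiation raised and lowered members of the same gene lists. GDF15 rose 4.28-fold (log2 2.10 ± 0.24 SE, n = 3, limma adjusted p = 2.59e-05), from 7.36 ± 0.38 to 9.45 ± 0.04 (SD), and CDKN1A rose 2.89-fold (1.53 ± 0.18, adjusted p = 3.98e-05). PHLDA3, which restrains AKT signalling, rose 2.62-fold, ATF3 by a log2 change of 1.25, PPM1D by 1.20, SESN1 by 1.18 and MDM2 by 1.06. TNFAIP8L1 fell 2.72-fold, PIF1 2.62-fold, CCNF, cyclin F, 2.38-fold, CDCA8 2.36-fold, AURKA, the mitotic kinase Aurora A, 2.35-fold (-1.23 ± 0.11, adjusted p = 1.23e-06), and SGO2, a protector of centromeric cohesion, 2.32-fold. The kinesin gene KIF18A fell by 1.15 on the log2 scale. Of 62 p53 targets 19 rose (32 adjusted over the list alone). The list had a median of 0.43, and 0.41 to 0.53 within chips (camera adjusted p = 1.79e-37, or 4.62e-05 with an estimated correlation). Of 65 G2/M genes 28 fell (45 adjusted over the list alone). That list had a median of -0.49, and -0.59 to -0.45 within chips (camera adjusted p = 6.96e-51, or 4.03e-05 with an estimated correlation). In all, 29 genes rose and 65 fell; these were 65 and 159 with the chip as a block, and 53 and 163 with the replicate as a block. The 94 called genes changed the same way within each of the 3 chips. The count was 57 without unirradiated replicate 2, 59 without unirradiated replicate 3, and 17 with only these 6 arrays fitted, without PHLDA3, TNFAIP8L1, CCNF and SGO2.

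In p53-depleted cells the fall of mitotic genes was called again, and few p53 targets passed the test. CDKN1A rose 2.36-fold (log2 1.24 ± 0.18 SE, n = 3, limma adjusted p = 0.0012), from 10.43 ± 0.09 to 11.67 ± 0.29 (SD). SESN1 rose 1.65-fold (0.72 ± 0.11, adjusted p = 0.0012) and TP53INP1 2.71-fold (adjusted p = 0.0175), and these 3 were all the genes that rose. TP53INP1 was above background on 2 of the 3 unirradiated arrays (4.96 ± 0.51 SD there), so its fold is uncertain. PIF1 fell 2.78-fold (-1.47, adjusted p = 5.75e-06), and BORA, TNFAIP8L1, CENPA, PSRC1, FAM83D and CENPE, a kinetochore motor, fell by 1.14, 1.14, 1.14, 1.12, 1.08 and 1.01 on the log2 scale. MDM2 changed by 0.46 (adjusted p = 1) and GDF15 by 0.69 (adjusted p = 0.758), neither of them called. Of 62 p53 targets, 3 rose (3 adjusted over the list alone). The list had a median of 0.21, and 0.13 to 0.25 within chips (camera adjusted p = 2.89e-10, or 0.0247 with an estimated correlation). Of 65 G2/M genes 14 fell (38 adjusted over the list alone). That list had a median of -0.40, and -0.45 to -0.30 within chips (camera adjusted p = 1.13e-71, or 4.77e-06 with an estimated correlation). None of 17 histone genes was called over all genes and 5 fell adjusted over the list alone. The histone list had a median of -0.27, and -0.45 to -0.18 within chips (camera adjusted p = 1.78e-11, or 0.00508 with an estimated correlation). The DNA replication list had a median of 0.09, and 0.07 to 0.10 within chips (camera adjusted p = 0.0252; adjusted p = 0.812 with an estimated correlation); it was lost without unirradiated replicate 1 or 2 or irradiated replicate 3 (adjusted p up to 0.362). In all, 3 genes rose and 28 fell, 8 and 42 with the chip as a block, and 7 and 42 with the replicate as a block; all 31 went the same way within each of the 3 chips. The count was 17 without unirradiated replicate 2, 20 without irradiated replicate 2 and 15 without irradiated replicate 3. The TP53INP1 call was lost without replicate 2 or 3 of either dose (adjusted p 0.0561 to 0.176) and with the authors' values. With only these 6 arrays fitted the count was 5, without CDKN1A, SESN1, TP53INP1, FAM83D and CENPE.

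With the NFBD1 and p53 shRNAs together, CDKN1A was the 1 gene that rose, 2.05-fold (log2 1.04 ± 0.18 SE, n = 3, limma adjusted p = 0.00721). That call was lost without unirradiated replicate 2 or 3 or irradiated replicate 2 (adjusted p 0.0652 to 0.095). PIF1 fell 2.85-fold (-1.51, adjusted p = 3.69e-06), and TNFAIP8L1, CCNF, CENPE, PSRC1 and AURKA fell by 1.22, 1.19, 1.14, 1.08 and 1.01 on the log2 scale. MDM2 changed by 0.09 (adjusted p = 0.999) and GDF15 by 1.05 (adjusted p = 0.112), neither of them called. Of 62 p53 targets 1 rose (7 adjusted over the list alone). The list had a median of 0.16, and 0.11 to 0.23 within chips (camera adjusted p = 2.47e-11, or 0.0173 with an estimated correlation). Of 65 G2/M genes 17 fell (43 adjusted over the list alone). That list had a median of -0.44, and -0.57 to -0.33 within chips (camera adjusted p = 8.36e-84, or 2.64e-06 with an estimated correlation). The histone list, with no called member, had a median of -0.13, and -0.18 to -0.07 within chips (camera adjusted p = 0.00378; adjusted p = 0.287 with an estimated correlation), and was lost without irradiated replicate 1 (adjusted p = 0.151). In all, 1 gene rose and 24 fell, 5 and 40 with the chip as a block, and all 25 went the same way within each of the 3 chips. The count was 13 without unirradiated replicate 2, and 5 with only these 6 arrays fitted, without CDKN1A and CCNF.

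**Figure D2:**
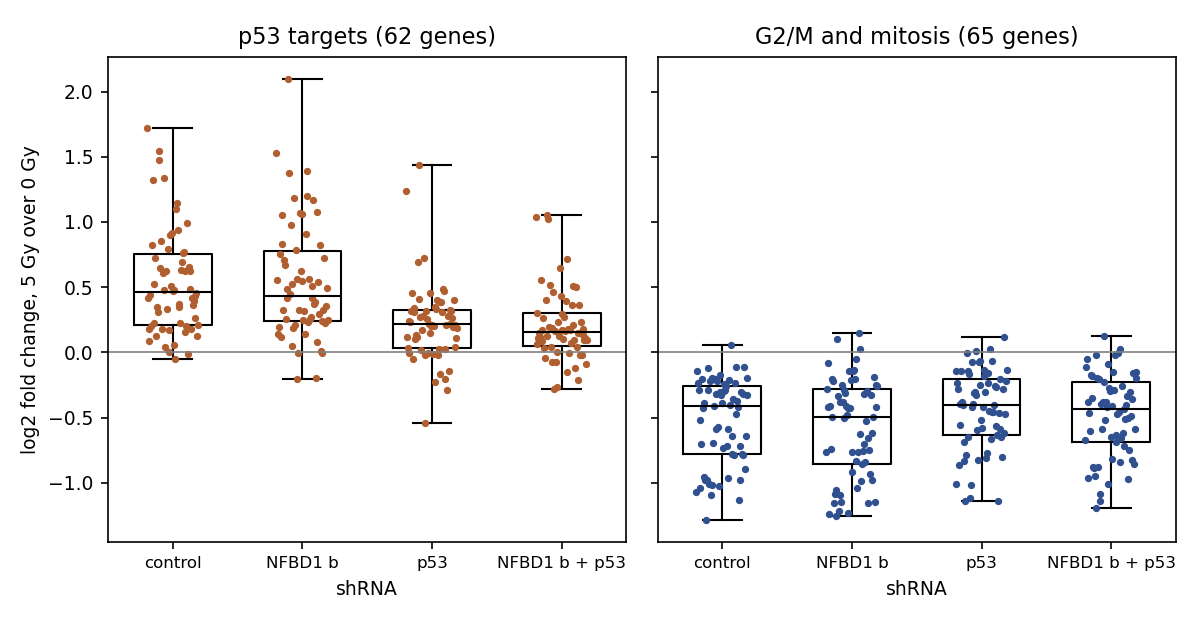
Log2 fold change from 0 to 5 Gy of each of the 62 p53 targets and 65 G2/M genes (points) with the 4 shRNA treatments on the horizontal axis; boxes span the quartiles with a line at the median, and whiskers reach the extremes. The median of the p53 targets was 0.46, 0.43, 0.21 and 0.16 with the control, NFBD1, p53 and both shRNAs, and that of the G2/M genes -0.41, -0.49, -0.40 and -0.44.

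After irradiation, 20 genes were called with all 4 shRNA treatments. CDKN1A was the 1 gene that rose in all 4, and 19 fell in all 4, among them AURKA, CENPA, CENPE, HJURP, which loads CENPA, NEK2, a centrosomal kinase, CCNA2, cyclin A2, and PIF1; 12 of the 19 stood on the G2/M list. HJURP, NEK2 and CCNA2 were chosen after their values were seen. The log2 changes with the control shRNA correlated across 12419 genes with those of hairpin b at 0.37 (Pearson; Spearman 0.25; jackknife SE 0.12), of the p53 shRNA at 0.29 (Spearman 0.19; SE 0.09) and of both shRNAs at 0.27 (Spearman 0.15; SE 0.08). The control and hairpin b shared 62 called genes, 21 higher and 41 lower in both, where independent lists would share 0.0607 and 0.246.

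Whether the response depended on p53 or NFBD1 was tested by interaction. No gene passed limma's test for a different response with the p53 shRNA (0 called, 210 at an unadjusted p under 0.05), and with the authors' values 1 did, SESN1 (log2 difference -0.55, adjusted p = 0.00291). Without any effect, a share of 0.05 of the 12419 genes would lie under that p, which is more than 210. The fit without a block leaves chip differences in the residual, so this test may be too strict. Fitting the chip as a block called 0 genes too. The smallest p belonged to PPM1D, whose log2 change was smaller by -0.82 (SE 0.17, limma adjusted p = 0.854), followed by GRHL3, which was above background only in irradiated control cells and has no measured difference, and SESN1 (-0.61). Adjusted over the list alone, 5 p53 targets responded less, SESN1, SESN2, PPM1D, TRIAP1 and TIGAR, of which TRIAP1 and TIGAR were chosen after their values were seen. As a list, the 62 p53 targets had a median difference of -0.27, and -0.29 and -0.35 within the 2 chips that hold both treatments (camera adjusted p = 7e-23, or 0.000718 with an estimated correlation). Of these 62, 59 lay below 0. The G2/M list had a median difference of 0.10, and 0.00411 and 0.18 within chips (camera adjusted p = 0.0262; adjusted p = 0.737 with an estimated correlation), and the DNA replication list also of 0.10, and 0.07 and 0.12 within chips (camera adjusted p = 0.0471; adjusted p = 0.911 with an estimated correlation). The histone list had a median difference of -0.15, which was 0.14 within chip 1 and -0.17 within chip 3 (camera adjusted p = 0.0413; adjusted p = 0.517 with an estimated correlation). The G2/M call was lost without unirradiated p53 replicate 1 or 3, irradiated p53 replicate 1, unirradiated control replicate 2 or 3, or irradiated control replicate 3 (adjusted p up to 0.346). The DNA replication call was lost without unirradiated p53 replicate 1 or 2, irradiated p53 replicate 3, unirradiated control replicate 2 or 3, or irradiated control replicate 1 or 2 (up to 0.412). The histone call was lost without irradiated p53 replicate 1 or 3, unirradiated p53 replicate 2, unirradiated control replicate 2, or irradiated control replicate 2 or 3 (up to 0.763).

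No gene passed limma's test for a different response with hairpin b (0 called, 385 at an unadjusted p under 0.05). That count too was below a share of 0.05 of the 12419 genes, so the test may be too strict. The smallest p-values belonged to SKIC3 (log2 difference -1.13), UNK (-0.65) and PALD1. PALD1 was not above background on any array of irradiated hairpin-b or unirradiated control cells and has no measured difference. The 17 histone genes had a median difference of 0.12, and 0.11 and 0.13 within chips, with no called member (camera adjusted p = 0.0413; adjusted p = 0.517 with an estimated correlation). That call was lost without unirradiated control replicate 1 or 3, irradiated control replicate 1 or 2, unirradiated hairpin-b replicate 2, or irradiated hairpin-b replicate 2 or 3 (adjusted p up to 0.256).

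The effect of hairpin b was taken by setting it against the control shRNA. On its own that comparison cannot tell loss of NFBD1 from other effects of the hairpin. In unirradiated cells (n = 3 against 3), 5 genes rose and 50 fell. INHBE, a subunit of activin E, rose 2.89-fold (log2 1.53 ± 0.27 SE, limma adjusted p = 0.00432), from 6.12 ± 0.06 to 7.66 ± 0.04 (SD). MYADM, a membrane protein, fell 2.82-fold (-1.50 ± 0.13, adjusted p = 1.39e-06), from 10.17 ± 0.02 to 8.68 ± 0.18, and CAV2, caveolin 2, fell 2.59-fold (-1.37 ± 0.12, adjusted p = 8.66e-07). EIF2S1, the alpha subunit of the translation initiation factor eIF2, fell 2.17-fold (-1.12, adjusted p = 0.00293), RFC5, a subunit of the clamp loader of DNA replication, 2.24-fold (adjusted p = 0.00861), and LAMP2, a lysosomal membrane protein, 2.14-fold (-1.10, adjusted p = 1.26e-05), although 2 of LAMP2's 5 other probes shared its direction. HPS3 fell by 1.11 on the log2 scale. JDP2, PTBP2, OR51B5 and FAM107B, the other genes that rose, had log2 changes of 0.88, 0.80, 0.78 and 0.69. FAM107B was lost without any 1 of the 6 arrays, PTBP2 without any but control replicate 3, JDP2 without any but control replicate 1, and OR51B5 without control replicate 2 or 3 or hairpin-b replicate 1 or 2 (adjusted p 0.0626 to 0.329 over the 4 genes). JDP2 was also lost with the authors' values, without background correction, without the detection filter, with each probe tested on its own and with trend and robust moderation, and FAM107B with each probe tested on its own. HPS3 was lost without hairpin-b replicate 1 or control replicate 2 (0.0614 to 0.0932), and RFC5 without hairpin-b replicate 1 or control replicate 1 or 3 (0.0545 to 0.0574). The chip as a block gave 16 genes that rose and 116 that fell, and the replicate as a block 16 and 106. All 55 went the same way within chips 1 and 2. The count was 31 without hairpin-b replicate 1, 28 without control replicate 2, 35 without control replicate 3, and 19 with only these 6 arrays fitted, without MDC1, HPS3 and the rises other than INHBE.

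After 5 Gy, 9 genes rose and 135 fell with hairpin b. MYADM fell 3.15-fold (log2 -1.66, n = 3, limma adjusted p = 1.38e-07), AMMECR1 2.67-fold (-1.42 ± 0.11 SE, adjusted p = 1.1e-07), CDH2, N-cadherin, 2.43-fold (-1.28 ± 0.10, adjusted p = 1.1e-07), LAMP2 2.59-fold (3 of its 5 other probes lower too), PRRC1 2.58-fold and EIF2S1 2.57-fold (adjusted p = 0.00024). MTRR, methionine synthase reductase, fell by 1.24 on the log2 scale (1 of its 2 other probes lower too) and RFC5 by 1.15 (adjusted p = 0.00661). OR51B5, annotated as an olfactory receptor, rose 1.85-fold (adjusted p = 0.00425) and SPX, the peptide hormone spexin, 1.62-fold (0.70 ± 0.13, adjusted p = 0.00737). When the chip was a block 38 genes rose and 281 fell, and with the replicate as a block 42 and 272. All 144 went the same way within chips 1 and 2, and 142 had no overlap between groups, where 12.5% of all genes had none (10% by chance). For these 142 the direction within chips follows from the lack of overlap and is no separate check. The count was 82 without control replicate 1, control replicate 2 or hairpin-b replicate 2, and 10 with only these 6 arrays fitted, without OR51B5, SPX and RFC5.

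In p53-depleted cells hairpin b was set against the p53 shRNA alone. Without irradiation 6 genes rose and 57 fell (n = 3 against 3). INHBE rose 2.61-fold (log2 1.38, limma adjusted p = 0.0118) and PALM2, a paralemmin, 2.15-fold (1.10 ± 0.17 SE, adjusted p = 0.00165). MYADM fell 2.33-fold (-1.22, adjusted p = 3.1e-05), SLC66A3 2.17-fold (-1.12, adjusted p = 0.000194), and CAV2, LAMP2, TOPORS, a ubiquitin and SUMO ligase, and CHSY3, a chondroitin synthase, fell by 1.09, 1.09, 1.08 and 1.07 on the log2 scale. The chip block gave 21 genes that rose and 110 that fell, and the replicate block 26 and 112; all 63 went the same way within chips 3 and 4. The count was 29 without p53 replicate 1 and 36, 34 and 38 without double-depleted replicates 1, 2 and 3, and 14 with only these 6 arrays fitted, without MDC1, PALM2 and TOPORS. The INHBE call was lost without replicate 1 or 3 of either group (adjusted p 0.061 to 0.0822).

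After 5 Gy in p53-depleted cells, 7 genes rose and 81 fell with hairpin b. CHSY3 fell 2.53-fold (log2 -1.34 ± 0.17 SE, n = 3, limma adjusted p = 0.000113), LAMP2 2.45-fold (1 of its 5 other probes lower too), MYADM 2.32-fold, ATG4D, an autophagy protease, 2.29-fold, and PRRC1 and EIF2S1 by 1.19 and 1.10 on the log2 scale (EIF2S1 adjusted p = 0.00307). INHBE rose 2.60-fold (adjusted p = 0.0104). PALM2, not above background with the p53 shRNA alone, was at least 1.67-fold higher (adjusted p = 0.00875). PANK1, a pantothenate kinase, was the 1 p53 target called (-0.69; 1 of its 2 other probes lower too). Blocking on the chip gave 33 rises and 160 falls, and blocking on the replicate 35 and 186; all 88 went the same way within chips 3 and 4. The count was 46, 56 and 50 without p53 replicates 1, 2 and 3, and 55 and 51 without double-depleted replicates 2 and 3, and 17 with only these 6 arrays fitted, without EIF2S1, PALM2 and PANK1. INHBE was lost without p53 replicate 1 or 3 or double-depleted replicate 2 (adjusted p 0.0501 to 0.0945), PALM2 without p53 replicate 2 or double-depleted replicate 3 (0.0604 to 0.0829) and with the authors' values, and PANK1 without replicate 3 of either group (0.0577 to 0.0976).

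Among the gene lists, ER stress and amino acid response genes were higher with hairpin b. With the control shRNA as reference, the median log2 change of its 31 members was 0.15 (0.13 with the chip as a block, 0.07 and 0.11 within chips; camera adjusted p = 0.0075; adjusted p = 0.0653 with an estimated correlation), and it was lost without hairpin-b replicate 2 (0.0561). After 5 Gy it was 0.20, with 0.12 under the chip block and 0.13 within both chips (camera adjusted p = 0.00262, or 0.0363 with an estimated correlation). In p53-depleted cells it was 0.20, with 0.16 under the chip block and 0.18 and 0.20 within chips (camera adjusted p = 2.59e-05, or 0.00532 with an estimated correlation). After 5 Gy in those cells it was 0.26, with 0.26 under the chip block and 0.24 and 0.31 within chips (camera adjusted p = 1.68e-06, or 0.00211 with an estimated correlation). None of the 31 members was called over all genes, and 1, 0, 3 and 4 rose adjusted over the list alone; the last 4 were DDIT3, PSPH, SESN2 and CTH, chosen after their values were seen. With the replicate as a block, SESN2 and CTH passed over all genes at 0 Gy and SESN2 and PSPH at 5 Gy in p53-depleted cells. For the second hairpin the ER stress list went the other way, with a median of -0.11 (camera adjusted p = 0.0194, and adjusted p = 0.326 with an estimated correlation). The rise of this list was thus not shared by the 2 NFBD1 hairpins. The interferon list was called in p53-depleted cells, with a median of 0.09 (chip block 0.14, within chips 0.04 and -0.04; camera adjusted p = 0.0341; adjusted p = 0.948 with an estimated correlation) and after 5 Gy of 0.16 (chip block 0.17, within chips 0.03 to 0.12; camera adjusted p = 0.00184; adjusted p = 0.737 with an estimated correlation). The first of these was lost without double-depleted replicate 1 or p53 replicate 3 (adjusted p up to 0.999) and the second without double-depleted replicate 1 (0.178). The p53 targets were not called with hairpin b, with a median of 0.00527 without irradiation (camera adjusted p = 0.928) and 0.01 after 5 Gy (camera adjusted p = 0.921), where the means, -0.00563 and -0.00348, had the opposite sign and the test pointed down and up.

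Hairpin b changed overlapping genes with and without p53 depletion. Of 177 genes called in any of its 4 comparisons 39 were called in all 4, of which INHBE and OR51B5 rose and 37 fell. The log2 changes with and without p53 depletion correlated across 12419 genes at 0.51 in unirradiated cells (Pearson; Spearman 0.43; jackknife SE 0.08) and at 0.52 after 5 Gy (Spearman 0.44; SE 0.16). In unirradiated cells 41 called genes were shared, 39 of them lower in both, where independent lists would share 0.229, and after 5 Gy 68 were shared, 64 of them lower in both, where independent lists would share 0.881. No gene passed limma's test for an effect of hairpin b that differs with p53 depletion: 0 were called at 0 Gy (154 at an unadjusted p under 0.05), with the smallest p-values for CRYBG3 (log2 difference -0.88), C1orf21 and NTRK3. At 5 Gy 0 were called too (248 at an unadjusted p under 0.05), with the smallest p-values for ZNF92 (-0.87), EPHX2 and CIMAP1D. Both unadjusted counts were below a share of 0.05 of the 12419 genes, so these tests may be too strict as well. C1orf21, NTRK3, EPHX2 and CIMAP1D were each not above background on any array of at least 1 of the groups compared, so their differences were not measured.

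**Figure D3:**
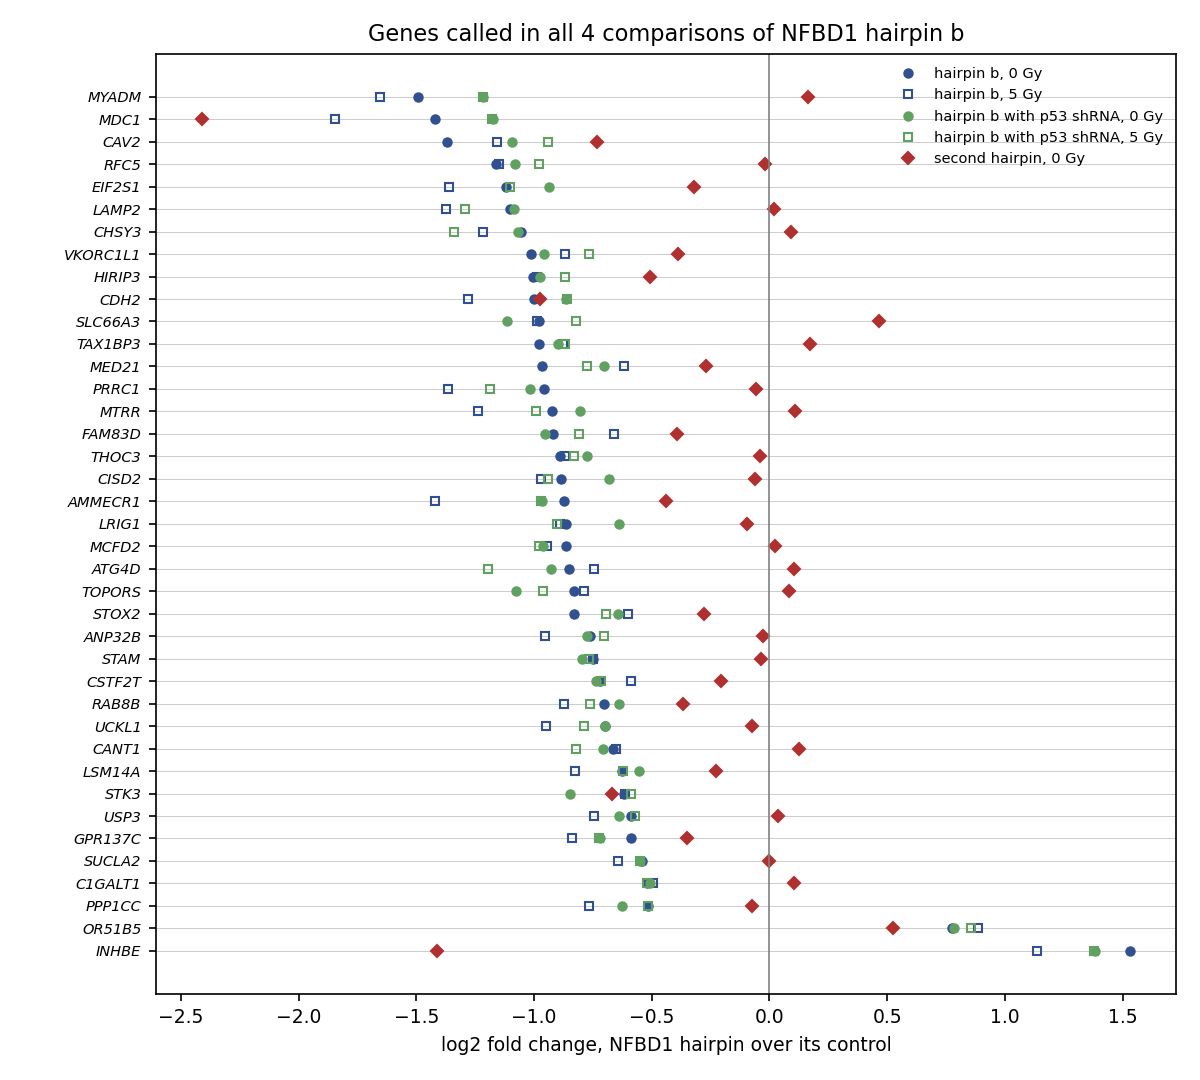
Log2 fold change of the 39 genes called in all 4 comparisons of hairpin b (one line per gene on the vertical axis), with a point for each of these comparisons and a diamond for the second hairpin. INHBE lay at 1.53 and 1.38 in unirradiated cells with hairpin b and at -1.41 with the second hairpin, and MDC1 was lower with each hairpin.

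The p53 shRNA was set against the control shRNA. In unirradiated cells 40 genes fell and 1 rose (n = 3 against 3). CDKN1A fell 2.40-fold (log2 -1.26 ± 0.18 SE, limma adjusted p = 0.00134), from 11.69 ± 0.36 to 10.43 ± 0.09 (SD). CCDC85C fell 2.32-fold (-1.21 ± 0.17, adjusted p = 0.00134), UBL3, a ubiquitin-like protein, 2.18-fold (-1.13 ± 0.12, adjusted p = 5.81e-05), MSH6, a mismatch repair gene, 2.12-fold (-1.08 ± 0.12, adjusted p = 6.15e-05), and CXADR, the coxsackievirus and adenovirus receptor, 2.09-fold (adjusted p = 0.000425). GDF15 fell 2.33-fold (adjusted p = 0.0243) and DDB2, a nucleotide excision repair gene, 2.00-fold (adjusted p = 0.0243). NTRK3, not above background in the control, was at least 1.14-fold higher (adjusted p = 0.0218). GDF15 was lost without any 1 array but control replicate 3, DDB2 without any but control replicate 2, and NTRK3 without any of the 6 (adjusted p 0.0522 to 0.218 over the 3 genes). These 3 were also lost with the authors' values, and NTRK3 without background correction and with trend and robust moderation. Of 62 p53 targets 7 fell (17 adjusted over the list alone). The list had a median of -0.28, with -0.32 under the chip block and -0.42 and -0.26 within chips (camera adjusted p = 3.71e-23, or 0.000718 with an estimated correlation). The ER stress list had a median of -0.12, with no called member (chip block -0.14, within chips -0.17 to -0.11; camera adjusted p = 0.0126; adjusted p = 0.0771 with an estimated correlation), and was lost without p53 replicate 1 or control replicate 2 (up to 0.261). With the chip as a block 5 genes rose and 86 fell, 40 of the 41 among them, and all 41 went the same way within chips 1 and 3. Leaving out any 1 of the 6 arrays gave 13 to 18 genes, and fitting only these 6 arrays gave 0 in limma (471 at an unadjusted p under 0.05).

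After 5 Gy 12 genes rose and 75 fell with the p53 shRNA. GDF15 fell 4.22-fold (log2 -2.08 ± 0.24 SE, n = 3, limma adjusted p = 6.95e-05), from 8.92 ± 0.33 to 6.84 ± 0.36 (SD), and CDKN1A 3.35-fold (-1.74 ± 0.18, adjusted p = 2.39e-05), from 13.41 ± 0.11 to 11.67 ± 0.29. MDM2 fell 2.69-fold (-1.43 ± 0.22, adjusted p = 0.000963), INKA2 2.70-fold, ACTA2, smooth muscle actin, 2.63-fold (adjusted p = 0.000774), SESN1 2.55-fold (-1.35 ± 0.11, adjusted p = 2.47e-07), ATF3 2.32-fold, SESN2 2.20-fold and MSH6 1.86-fold. GCNT1, a glycosyltransferase, rose 1.69-fold (adjusted p = 0.00718), SLC30A2, a zinc transporter, 1.68-fold (adjusted p = 0.00604), and CDK5R1, an activator of CDK5, 1.55-fold (adjusted p = 0.00591). GCNT1 was lost without p53 replicate 1 or control replicate 2 (adjusted p 0.0632 to 0.0688), SLC30A2 without p53 replicate 1 (0.0585) and CDK5R1 without replicate 3 of either group (0.0508 to 0.0533). With the chip as a block 38 genes rose and 141 fell, and all 87 went the same way within chips 1 and 3. Leaving out any 1 of the 6 arrays gave 36 to 57 genes, and fitting only these 6 arrays gave 24, without GCNT1, SLC30A2 and CDK5R1.

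Of the 62 p53 targets 24 fell with the p53 shRNA after 5 Gy (42 adjusted over the list alone). The list had a median of -0.60, with -0.63 under the chip block and -0.62 and -0.70 within chips (camera adjusted p = 9.58e-58, or 4.45e-06 with an estimated correlation). The G2/M list, with no called member, was higher, with a median of 0.13 (chip block 0.14, within chips 0.15 and 0.16; camera adjusted p = 0.0028; adjusted p = 0.517 with an estimated correlation), and was lost without p53 replicate 1 or control replicate 3 (adjusted p up to 0.102). The DNA replication list had a median of 0.13 (chip block 0.09, within chips 0.08 and 0.14; camera adjusted p = 0.000263; adjusted p = 0.458 with an estimated correlation), and 1 of its 58 members rose, CDC25A (0.55), a call lost without any 1 array but p53 replicate 2 (adjusted p 0.121 to 0.273), with each probe tested on its own or with only these 6 arrays fitted. The ER stress list had a median of -0.11, with -0.06 under the chip block and -0.14 and -0.08 within chips (camera adjusted p = 0.00205, or 0.0332 with an estimated correlation). In that list 1 member fell, SESN2 (2 adjusted over the list alone).

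The second NFBD1 hairpin was set against its own control in unirradiated cells on chip 5 (n = 3 against 3), and 1503 genes rose and 1393 fell of 11040, with 43 and 39 of them changed at least 2-fold. KYNU, an enzyme of tryptophan breakdown, rose 5.91-fold (log2 2.56 ± 0.07 SE, limma adjusted p = 2.33e-07), from 6.56 ± 0.07 to 9.12 ± 0.08 (SD), and CXCL8, the chemokine interleukin 8, 5.16-fold (2.37 ± 0.10, adjusted p = 1.57e-06). ODAPH rose 4.98-fold, the keratin-associated KRTAP2-4 3.60-fold, the hair keratin KRT34 3.27-fold, SP140 3.18-fold, the trypsin inhibitor SPINK1 3.11-fold and the defensin DEFB103B 3.01-fold. After MDC1, the largest falls were of HAPLN1, a link protein of the matrix, 3.67-fold, ACKR3, an atypical chemokine receptor, 3.45-fold, CRYAB, a small heat shock protein, 3.40-fold, EIF4EBP2, a repressor of translation initiation, 3.16-fold, CAPSL 3.00-fold, PKIB 2.76-fold and INHBE 2.66-fold (-1.41 ± 0.16, adjusted p = 0.000272). The whole comparison lies on 1 chip, and 2873 of the called genes had no overlap between groups, where 42% of all genes had none (10% by chance).

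Cell cycle and p53 genes moved with the second hairpin. Of 65 G2/M genes 45 fell (55 adjusted over the list alone), with a list median of -0.30 (camera adjusted p = 9.99e-17, or 0.0332 with an estimated correlation). Those that fell included the checkpoint kinases BUB1B and TTK (-0.50 and -0.49), the phosphatase CDC25C (-0.48) and CENPA (-0.48), and all 65 lay below 0. Of 63 p53 targets 30 rose and 2 fell (33 and 2 adjusted over the list alone; median 0.21; camera adjusted p = 8.5e-07; adjusted p = 0.0744 with an estimated correlation), with CDKN1A 1.78-fold higher (0.83 ± 0.07 SE, limma adjusted p = 4.81e-05), CYFIP2 and RRM2B higher by 0.94 and 0.85, and DDIT4 2.54-fold lower. Of 19 NF-kB and inflammatory genes 15 rose and 2 fell, the same numbers as adjusted over the list alone (median 0.40; camera adjusted p = 9.57e-06; adjusted p = 0.0714 with an estimated correlation), with the chemokine CCL20 2.18-fold higher, SOD2 higher by 0.85, and IL1A at least 1.41-fold higher (limma adjusted p = 0.000948). Of 16 histone genes 10 fell, such as H4C14 and H3C10 (-0.65 and -0.58), with 1 higher and 11 lower adjusted over the list alone (median -0.32; camera adjusted p = 0.00038; adjusted p = 0.117 with an estimated correlation). Of 59 DNA replication genes 1 rose and 19 fell, such as DUT and E2F2 (-0.63 and -0.43), with 1 and 20 adjusted over the list alone (median -0.14; camera adjusted p = 2.59e-05; adjusted p = 0.256 with an estimated correlation).

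The remaining lists with a call for the second hairpin were the ER stress, DNA damage and neural lists. Of 31 ER stress genes 4 rose and 11 fell, over all genes and adjusted over the list alone (median -0.11; camera adjusted p = 0.0194; adjusted p = 0.326 with an estimated correlation), with PHGDH and PCK2, of serine and phosphoenolpyruvate synthesis, lower by a log2 change of -0.56 and -0.54 and PPP1R15A higher by 0.61. Of 48 DNA damage genes 6 fell, such as H2AX, BRCA1 and CHEK1 (-0.43, -0.36 and -0.36), and 6 adjusted over the list alone (median -0.08; camera adjusted p = 0.0387; adjusted p = 0.368 with an estimated correlation). Of 8 neural markers 1 rose and 6 fell, such as TUBB3 and NCAM1 (-0.64 and -0.60), and the numbers adjusted over the list alone were the same (median -0.43; camera adjusted p = 0.0377; adjusted p = 0.387 with an estimated correlation). The DNA damage call was lost without control replicate 1 or hairpin replicate 2 (adjusted p up to 0.0768), and the neural call without hairpin replicate 2 (0.0759) and with the authors' values (0.0667).

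The changes with the 2 NFBD1 hairpins were then compared. Across 10910 genes their log2 changes in unirradiated cells correlated at 0.10 (Pearson 0.0988; Spearman 0.1; jackknife SE 0.15), and without hairpin-b replicate 1 at -0.01. Of the 55 genes called with hairpin b 20 were also called with the second hairpin, 14 lower in both, where independent lists would share 6.34, and 1 higher in both, where they would share 0.675. In a fit of all 30 arrays, added after seeing the data, the effects of the hairpins differed for 347 genes, 175 higher and 172 lower with hairpin b. MYADM and LAMP2 were lower with hairpin b by a log2 difference of -1.67 and -1.12, and CAV2, lower with each (-1.37 and -0.73), by -0.64 (limma adjusted p = 0.0168). CDH2, also lower with each, had a difference of -0.04 (adjusted p = 0.959), and the difference of MDC1 was 1.00 (adjusted p = 0.079). No chip held both hairpins, so the chip and the hairpin cannot be told apart here.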

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

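All tests of the few changes shared by the NFBD1 hairpins, the within-chip values and the p53 depletion test of the p53 target list, and the spread of fold changes with the second hairpin were chosen only after the result was seen; the difference between the hairpins was itself added after seeing the data.

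Some responses differed between groups by a test of the difference itself. The radiation response of the p53 target list was smaller with the p53 shRNA, with a median difference of -0.269. With that shRNA the list differences were 0.104 for G2/M genes, 0.0999 for DNA replication genes and -0.153 for histone genes (0.143 within chip 1), and with hairpin b the histone difference was 0.118. These 4 differences are not firm: the calls were lost with an estimated correlation (adjusted p = 0.737, 0.911, 0.517 and 0.517 with an estimated correlation), and when any 1 of 6, 7, 6 and 7 of the 12 arrays was left out. The effects of the hairpins on unirradiated cells differed for 347 genes. Of the genes called with each hairpin, 5 went in opposite directions: INHBE (log2 difference, hairpin b minus second hairpin, 3.07), SLC66A3 (-1.45), F3, tissue factor (-1.08; limma adjusted p = 0.0203), INO80C, a chromatin remodelling subunit (-1.01), and FAM107B (0.99). F3 and INO80C were chosen after their values were seen.

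Few changes were shared by the NFBD1 hairpins. Noise that is independent between genes and hides shared changes is argued against. The 49 genes other than MDC1 that fell with hairpin b had a median of -0.85 there and of -0.0408 ± 0.0334 (bootstrap SE of the median) with the second hairpin. The SEs in this paragraph belong to medians over genes, which are not independent replicates. Noise shared by the genes of an array may not be in them. All 49 were also below 0 in p53-depleted cells, on other arrays (median -0.738 ± 0.0345), but 13 were called lower with the second hairpin too, such as CAV2 (-1.37 and -0.73), where independent lists would share 6.21. A candidate explanation for the others is that their changes belong to hairpin b and not to loss of its target, which stays a hypothesis, because 0 chips held both hairpins, and a difference between the 2 experiments cannot be told apart from one between the hairpins. Of 100 labellings of the arrays 3, the real one included, gave as many differing genes as it did (347; highest other 485), but the others as large were all among the 7 that kept the second experiment's own split, while the rest gave at most 24, so the count follows the second hairpin's changes and says nothing on chance in the difference between the hairpins.

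The p53 target genes responded less to radiation with the p53 shRNA. Chip differences that shift a gene equally at both doses cancel here by design, because both doses of a replicate shared a chip. The median difference was therefore -0.269 with and without the chip as a block, which is no test of such shifts. Within the chips that hold both treatments it was -0.291 and -0.346, so the smaller response was present on each of them. Compression of dim probes near the background is argued against. The 31 brighter genes of the list had a median difference of -0.276 ± 0.0413 (bootstrap SE). That SE belongs to a median over genes, which are not independent replicates. Depletion of p53 is a candidate explanation for the median difference of -0.269. The G2/M list, which fell in each treatment, moved by 0.104, towards a smaller fall. Whether that list is independent of p53 was not tested, so its smaller shift does not show an effect particular to p53 targets. Depletion of p53 remains a hypothesis, since the p53 transcript was not analysed here and 1 hairpin was used.

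Many more genes were called with the second hairpin (2896) than with hairpin b (55, or 132 with the chip as a block). The smaller spread between arrays in the second experiment is argued against as the whole cause: with noise of SD 0.209 added, at least 608 genes (median 717.5 of 20 draws) were still called. The same SD was added for all genes, so the chip differences within groups of the first experiment may not have been reproduced. The SD of log2 changes beyond the spread between arrays was 0.257 ± 0.00429 with the second hairpin and 0.116 ± 0.00403 with hairpin b. These SEs come from 200 draws of genes, which are not independent replicates. They therefore leave out the uncertainty from the few arrays and the separate experiments. Larger changes with the second hairpin may account for the count. The SD of log2 changes comes from the same values as the calls, so it is no separate check. Whether the depth of MDC1 depletion, another target of the hairpin or the separate experiment lies behind the larger changes was not tested. MDC1 fell further with the second hairpin, by a log2 difference of 1.00 (SE 0.309). That difference did not pass when adjusted over all 10910 genes (limma adjusted p = 0.079), which does not rule out a deeper depletion.

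The 6 arrays of a comparison split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. In all 11 comparisons of 2 groups 1 of the 10 splits, the real one, gave as many genes. For irradiation with the control, NFBD1, p53 and both shRNAs the real counts were 73, 94, 31 and 25 and the highest of the others 0, 1, 0 and 0. For hairpin b at 0 and 5 Gy they were 55 and 144 against 0 and 1, in p53-depleted cells 63 and 88 against 1 and 1, for the p53 shRNA 41 and 87 against 0 and 0, and for the second hairpin 2896 against 0. For the 4 interactions, with a real count of 0 in limma, 10 of 10 splits gave as many, the highest other being 1 for irradiation by NFBD1 (385 genes at an unadjusted p under 0.05) and 0 for the other 3 (210, 154 and 248). These 4 unadjusted counts were all below a share of 0.05 of the 12419 genes, so the interaction tests may be too strict.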

How the results depend on the processing

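The chip block and the arrays left out for the agreements between comparisons, and all settings for the difference between the hairpins, were chosen only after the result was seen. None of the 215 pairs of a named gene and a comparison in which it passed reversed its direction in any setting. Passing was lost for 13 of them with the authors' values, 10 with each probe tested on its own, 7 with trend and robust moderation, 4 without background correction, 4 with the replicate block, 3 without the detection filter, and 0 with all 30 arrays normalized together. It was lost for 0 of the 144 pairs tested with the chip block and 0 of the 199 tested with detection required on every array. Passing was also lost in 240 of 1290 fits of such a pair with 1 array left out, and 120 of 343 values within a chip, which have no test, moved by over 1 SD between replicates. It was lost for 70 of 144 pairs with only the groups compared, which leaves 4 residual degrees of freedom in place of 16. With only those groups counts fell to 28, 17, 5 and 5 for irradiation with the control, NFBD1, p53 and both shRNAs, and to 19 and 10 for hairpin b at 0 and 5 Gy. They were 0 (limma, 471 at an unadjusted p under 0.05) and 24 for the p53 shRNA, and 14 and 17 for hairpin b in p53-depleted cells. MDC1 no longer passed for hairpin b (-1.419, limma adjusted p = 0.0722) and in p53-depleted cells (-1.174, limma adjusted p = 0.0745), both at 0 Gy. The cause of these falls was not tested.

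With the chip as a block, counts were 224, 50 and 45 for irradiation with the NFBD1, p53 and both shRNAs, 132 and 319 for hairpin b, 91 and 179 for the p53 shRNA, and 131 and 193 for hairpin b in p53-depleted cells. With the replicate block they were 216 and 49 for irradiation with the NFBD1 and p53 shRNAs, 122 and 314 for hairpin b, and 138 and 221 in p53-depleted cells. For the p53 shRNA, where the numbers were not taken to pair the samples (lowest correlations -0.141 at 0 Gy and 0.089 at 5 Gy), that block gave 93 and 211 genes, with 73.5% lower in place of 86.2% at 5 Gy, and not every sample correlated best with its own number. The same held for irradiation with the control shRNA (0.0915; 103 genes) and for the second hairpin (correlations -0.0559 to 0.034; 2628 genes). Besides moving these counts, the replicate block ended no list call and added 1, and ended 4 named calls, all with the second hairpin (EBP, MSMO1, RAB7A and TFRC). Listed genes that had not passed did so with it, such as CCL2 and BCL2L1 with hairpin b. The cause of these differences was not tested.

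Leaving out 1 array gave 40 to 65, 57 to 92, 15 to 21 and 13 to 28 genes for irradiation with the control, NFBD1, p53 and both shRNAs, 28 to 41 and 82 to 126 for hairpin b, 13 to 18 and 36 to 57 for the p53 shRNA, 29 to 50 and 46 to 70 for hairpin b in p53-depleted cells, and 2156 to 2573 for the second hairpin; fewer arrays give less precision. MDC1 then ranged from -1.401 to -1.052 at 0 Gy and from -1.319 to -1.037 at 5 Gy in p53-depleted cells. Its change was -1.44 within chip 1 for hairpin b at 5 Gy and -0.78 within chip 4 in p53-depleted cells at 0 Gy. The correlation between the NFBD1 hairpins ran from -0.0103 (without unirradiated hairpin-b replicate 1) to 0.178, that of hairpin b with and without p53 depletion at 0 Gy from 0.418 to 0.509, and that of irradiation with the control and p53 shRNAs from 0.206 to 0.321. At 0 Gy the second of these was 0.604 without background correction, 0.652 with the authors' values and 0.609 with detection on every array. The irradiation response with the control shRNA correlated with the others at 0.497, 0.394 and 0.379 with the authors' values. The cause was not tested.

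Of the 37 list calls, 17 held with an estimated correlation, 37 with the chip block and 36 with the authors' values. The interferon list in p53-depleted cells at 0 Gy reversed within chip 4 (-0.0442) and ran from -0.0494 to 0.245 with 1 array left out, and the histone difference of irradiation by p53 reversed within chip 1 (0.143). The interactions stayed at 0 genes in limma in every setting but the authors' values, where irradiation by p53 gave 1 (SESN1). The difference between the hairpins called 283 genes, all among the 347, with each experiment normalized on its own. Signal over background limits the dim genes: 34.1% to 40.3% of probes were detected on an array, and changes of probes near the background are compressed or given as bounds.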

Other observations

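The correlations between further pairs of comparisons given last were chosen only after the result was seen.

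The following lists had no call as a whole with the second hairpin (n = 3 against 3), with which 2896 of all 11040 genes tested passed, and whether their members passed more often than other genes was not tested. Among 35 interferon response genes 3 rose and 6 fell, with IFIT1, an RNA-binding antiviral protein, at a log2 change of -0.79 and OASL at -0.41, and SP110 at 0.58 and ISG20, an exonuclease, at 0.42 (camera adjusted p = 0.911). Among 22 immediate early genes 7 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.152), with the phosphatases DUSP5 and DUSP1 at 0.93 and 0.63 and the nuclear receptor NR4A2 at 0.60. Among 33 apoptosis regulators 8 rose and 4 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.753), with CASP4 and BIRC2 at 0.68 and 0.60, and the inflammatory caspase CASP1 and BID at -0.96 and -0.68. Among 32 genes of the extracellular matrix and TGF-beta list 8 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.928), with the collagen genes COL1A1 and COL5A2 at -1.07 and -0.62, and ACTA2 and the matrix protease MMP3 at 1.05 and 0.90.

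Of 19 cholesterol synthesis genes 2 rose and 2 fell (camera adjusted p = 0.977), with HMGCS1 at 0.90. Of 7 epithelial markers CDH1, E-cadherin, rose (0.53) and KRT7 fell (-0.58; camera adjusted p = 0.801). Of 6 blood cell markers 2 rose, CD3D and CD68, a lysosomal protein of macrophages also found in other cells (1.24 and 1.01; camera adjusted p = 0.574), while the median was -0.0492 and the mean 0.296. For the interferon, cholesterol and matrix lists too the median and the mean differed in sign. Of 16 housekeeping genes 2 rose over all genes, RAB7A and TFRC (0.23 and 0.22), and 0 adjusted over the list alone; TFRC was lost without any 1 array but control replicate 1, and RAB7A without control replicate 2 or 3 or hairpin replicate 1 or 3 (limma adjusted p 0.0792 to 0.13), and each with the replicate as a block. Apart from the interferon list, none of these lists was called in any of the 15 comparisons, the smallest camera adjusted p being 0.0775 for the matrix list with hairpin b in p53-depleted cells after 5 Gy. ATF3, called in the first experiment, stood on the immediate early list and ACTA2 on the matrix list.

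The log2 changes of hairpin b with and without irradiation correlated across genes at 0.384 with 49 shared called genes, and those of the p53 shRNA at 0.488 with 27 shared called genes. With the chip as a block these correlations were 0.427 and 0.477. The comparisons share no arrays, but the 0 and 5 Gy arrays of a replicate share a chip and each pair of comparisons has the same imbalance of chips, so the values need not be 0 without an effect of the shRNA. Those of the second hairpin correlated with hairpin b after 5 Gy at 0.052 and with hairpin b in p53-depleted cells at 0.141. Genes are not independent replicates, and no explanation for these values was tested.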
